A study of Strongylocentrotus purpuratus with 2 samples.

How the data were processed

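The coelomocytes and the gut of 1 immune-challenged adult purple sea urchin (Strongylocentrotus purpuratus) were profiled by RNA sequencing, each as a single library. Both were collected 12 h after the challenge, per the labels. Coelomocytes are the free cells of the coelomic fluid and include the immune cells of the animal. Per the labels' protocols, the phagocytic fraction was separated on a density step gradient, whereas the gut was dissected and rinsed as whole tissue. Polyadenylated RNA was selected from total RNA and libraries were made for the SOLiD platform, per the labels' protocols.

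The deposited values were RPKM (read counts scaled by gene length in kilobases and by the number of mapped reads), 1 value per gene and library, computed by the authors and rounded to 2 decimals. Bowtie 0.12.7, a short-read aligner, is named in the submitters' processing notes. The genome build, the gene models and their lengths, the counting program, the treatment of reads that match several places and the read total used as denominator are not given in the sources used here. A value listed as 0.00 can stand for any level under 0.005 RPKM, so a listed 0 does not show that no read was seen. The RPKM unit removes gene length and read total but not composition: a gene that takes a large share of the reads of 1 library lowers all other values in that library.

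The total read count, and therefore the depth behind each value, is unknown. Steps of whole reads were searched for in the ratios of the low values (0.2 to 1 RPKM in both libraries, 2536 genes). The strongest candidate step pattern scored 1.43, and 37 of 200 smoothed resamplings without steps scored as high or higher, so no relative depth was recovered. On simulated whole-read data of 2000000 and 3000000, 8000000 and 4000000, or 30000000 and 15000000 reads for coelomocytes and gut the search detected steps each time, with 0 of 200 resamplings as high. The ratio it returned was right in the first case and off by a small whole factor in the other cases. No counting interval or detection floor was therefore computed for single genes.

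The table lists 29125 gene identifiers with no gene names. The reference name table supplied for the species (assembly Spur_5.0, 33503 genes) contains none of these identifiers (0 matched). The 28 gene lists fixed before the data were examined, which were patterns on gene names (immune receptors, effectors, digestive enzymes, tissue markers and others), could therefore not be applied, and no gene list result is given. No coordinates are given for the same reason. The identifiers named are the 2 with the largest log2 ratio in each direction among genes at 10 RPKM or more in the higher library. Other genes are described by their rank.

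The 2 columns were assigned to the tissues by name, and 0 further columns of sample values were present. With 1 library per tissue there are no replicates, so no test between the tissues was run and no p-value is given. The comparison used a rule of size: a gene counted as higher in a tissue if log2((coelomocyte RPKM + 0.5)/(gut RPKM + 0.5)) was at least 2 in its favour (4-fold) and the gene reached 1 RPKM in that tissue. The pseudocount of 0.5 understates the change of genes with low values. Alternatives were pseudocounts of 0.1 and 1, no minimum, minimums of 5 and 10 RPKM, 2-fold and 8-fold rules, and several rescalings of the libraries. The rescalings used the median log2 ratio of genes at 1 RPKM or more in both libraries, a trimmed mean of ratios (30% of ratios and 5% of levels removed from each side), the upper quartile, the summed RPKM, or quantities that leave out the 10 highest genes. The minimum of 10 RPKM and both rescalings that leave out the 10 highest genes were chosen after seeing the data, as were the level limits of 100, 300 and 1000 RPKM used to describe abundant genes.

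The rule was tested on simulated data in which the 29125 genes had their mean level in both libraries with an assumed noise SD of 0.3 on the log2 scale, which no replicate measures here, and 200 genes with a mean of at least 2 RPKM were raised in coelomocytes. It recovered 44.5% of the genes raised 4-fold, 97.0% of those raised 8-fold and 100% of those raised 16-fold among such genes. Genes raised 4-fold lay at the cut itself, and no counting error was simulated. The percentages therefore follow from the assumed noise and do not measure the rule on these libraries. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.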

Results

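Gene expression was measured in 2 tissues of 1 adult purple sea urchin 12 h after an immune challenge: isolated phagocytic coelomocytes and whole gut. Each tissue was represented by 1 library, so every difference below describes these libraries and has no replicate check. The table gave RPKM values for 29125 gene identifiers, of which 2255 were listed at 0 in both libraries. The read depth of the libraries is unknown. Summed over all genes, the values came to 413205 RPKM in coelomocytes and 249422 RPKM in gut, 1.66 times as much in coelomocytes.

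The first comparison addressed which genes each tissue expressed. At least 1 RPKM was reached by 13811 genes in coelomocytes and by 11525 genes in gut. Both tissues shared 8852 of these genes, 4959 reached 1 RPKM in coelomocytes alone and 2673 in gut alone. At the lower limit of 0.3 RPKM the tissues held nearly equal numbers, 18050 genes in coelomocytes and 17807 in gut. In the values as deposited, there were 4152 genes at 10 RPKM or more in coelomocytes against 2354 in gut, and 584 against 252 genes at 100 RPKM or more. These counts depend on the scale of the libraries. With gut values raised to equal summed RPKM, gut had 14196 genes at 1 RPKM or more, 3586 at 10 RPKM or more and 413 at 100 RPKM or more, and the genes reaching 1 RPKM in 1 tissue alone became 3489 in coelomocytes and 3874 in gut. Genes listed at 0 were about as frequent in both libraries, 13.6% in coelomocytes and 13.0% in gut.

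The gut transcriptome was dominated by a few genes, whereas the coelomocyte transcriptome was spread over more genes. The most abundant gut gene reached 47689 RPKM and held 19.1% of the summed RPKM of its library. It stood at 1125 RPKM in coelomocytes, where it ranked 42nd. The second gut gene stood at 17357 RPKM in gut and 1008 RPKM in coelomocytes. The 3 highest genes held 31.3% of the sum in gut and 7.10% in coelomocytes, and the 10 highest held 41.5% and 14.8%. A share of 50% of the sum was reached with 47 genes in gut and with 188 genes in coelomocytes.

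Some of the most abundant transcripts were common to both tissues. Of the 10 highest genes of each library, 4 were shared. The third-ranked gene was the same in both, at 8519 RPKM in coelomocytes and 12957 RPKM in gut. The other 3 shared genes ranked 1, 2 and 4 in coelomocytes (10922, 9877 and 8362 RPKM) and 5, 7 and 6 in gut (3571, 3497 and 3507 RPKM). Among the 100 highest genes, 20 were shared. Lists drawn independently from all 29125 identifiers, including those listed at 0 in both tissues, would share 0.343, which is a low bar. Across genes at 1 RPKM or more in both tissues, levels were moderately correlated (Spearman's rho 0.50, Pearson's r 0.55 on log2 values). Over all genes in the table Spearman's rho was 0.64. These are correlations across genes, which are not independent replicates.

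The second comparison addressed how the tissues differed gene by gene. By the 4-fold rule, 4042 genes were higher in coelomocytes and 1603 were higher in gut, so coelomocytes held 71.6% of the genes past the rule. This split depended on how the libraries were scaled. The median log2 ratio of coelomocytes over gut was 0.56 among genes expressed in both tissues (interquartile range -0.18 to 1.45). With that median set to 0, the counts were 2808 and 2364 genes, a coelomocyte share of 54.3%. With the libraries scaled to equal summed RPKM they were 2503 and 2593 genes (49.1%), and with upper-quartile scaling 2143 and 2939 genes (42.2%).

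**Figure D1:**
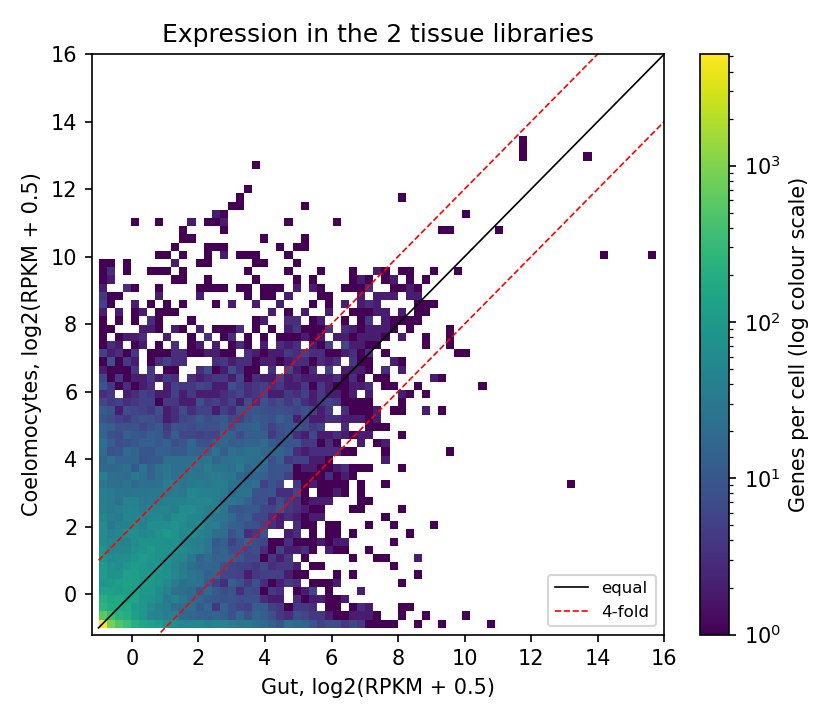
Expression of all 29125 genes in gut (horizontal axis) and coelomocytes (vertical axis), both as log2(RPKM + 0.5); the colour gives the number of genes per cell on a log scale, the solid line marks equal values and the dashed lines a 4-fold difference. More genes lie above the upper dashed line (4042 with at least 1 RPKM in coelomocytes) than below the lower dashed line (1603 with at least 1 RPKM in gut).

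Genes past the 4-fold rule were found in every group of mean level from 0 upward. With genes grouped by their mean log2(RPKM + 0.5) over both tissues, 38.1% of the 4933 genes with a mean from 1 to 2 passed the rule, 39.5% of the 3161 genes from 2 to 3, 34.4% of the 1652 genes from 3 to 4, 36.9% of the 837 genes from 4 to 5 and 39.3% of the 728 genes above 5. In the lowest of these groups, with a mean from 0 to 1, 22.3% of 6064 genes passed, and there the pseudocount draws the values together. The picture depends on the grouping. By the value in the higher library, the percentage rose from 9.97% of 5635 genes at 1 to 3 RPKM to 70.5% of 712 genes at 100 RPKM or more. Part of this rise is built in, since the pseudocount keeps genes near 1 RPKM from passing. Grouping by the higher value also selects for large ratios. Among the 728 genes with the highest mean, 230 were higher in coelomocytes and 56 in gut. Large differences were found in both directions: 536 genes were at least 32-fold higher in coelomocytes and 245 at least 32-fold higher in gut, and 164 and 48 genes passed a 128-fold rule.

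The widest contrasts paired high expression in one tissue with values under 1 RPKM in the other. SPU_005182 had the largest log2 ratio towards coelomocytes at the pseudocount of 0.5, with 2032.59 RPKM there and 0.55 RPKM in gut (log2 ratio 10.92). SPU_018884 followed with 917.47 RPKM in coelomocytes and was listed at 0 in gut. Towards gut, SPU_001467 stood at 1754.42 RPKM in gut and 0.05 RPKM in coelomocytes (log2 ratio -11.64), and SPU_018919 at 1105.68 and 0.18 RPKM (log2 ratio -10.67). They ranked 9 and 11 among all genes in gut. The size and order of these ratios depend on the pseudocount, and at 0.1 SPU_018884 came before SPU_005182. Their direction could not have changed under the settings tried, since a pseudocount keeps the sign and the largest rescaling moved log2 ratios by only 1.27. At 10 RPKM or more in coelomocytes, 954 genes stayed under 1 RPKM in gut and 92 of these were listed at 0. In the opposite direction 457 genes at 10 RPKM or more in gut stayed under 1 RPKM in coelomocytes, and 54 were listed at 0, again at the deposited scale.

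Many of the most abundant coelomocyte genes had very low values in gut, the only other tissue measured. Of the 222 genes at 300 RPKM or more in coelomocytes, 96 (43.2%) had under 1% of that level in gut. Of the 52 genes at 1000 RPKM or more, 32 (61.5%) did. In the opposite direction, 12 of the 59 genes at 300 RPKM or more in gut (20.3%) and 42 of the 252 genes at 100 RPKM or more (16.7%) had under 1% of their gut level in coelomocytes. Of the 584 genes at 100 RPKM or more in coelomocytes, 170 (29.1%) had under 1% of that level in gut. The median abundant gene kept 2.16% of its coelomocyte level in gut at the 300 RPKM limit, against 38.7% in the opposite direction. These shares were taken from the values as deposited, and rescaling the libraries moves the 2 directions towards each other. For the genes at 300 RPKM or more as deposited, the medians became 3.58% and 23.3% with equal summed RPKM. They became 5.21% and 16.04% with each library divided by its sum without its 10 highest genes. Under these rescalings 85 and 78 of the 222 coelomocyte genes, and 12 and 13 of the 59 gut genes, had under 1% in the other tissue.

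The abundant coelomocyte genes with low gut values differed in how low these were. The genes ranked 5, 6, 8, 9 and 10 in coelomocytes (6725, 4318, 3166, 3074 and 2855 RPKM) had gut values of 12.9, 10.2, 8.99, 9.69 and 7.62 RPKM, or 0.192%, 0.236%, 0.284%, 0.315% and 0.267% of the coelomocyte level. Of the genes at 300 RPKM or more in coelomocytes, 19 had a gut value above 0 but under 0.05% of the coelomocyte level, a limit set after seeing the data. They stood at 308 to 2033 RPKM in coelomocytes and at 0.02 to 0.55 RPKM in gut. A further 7 genes, at 320 to 917 RPKM in coelomocytes, were listed at 0 in gut.

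**Figure D2:**
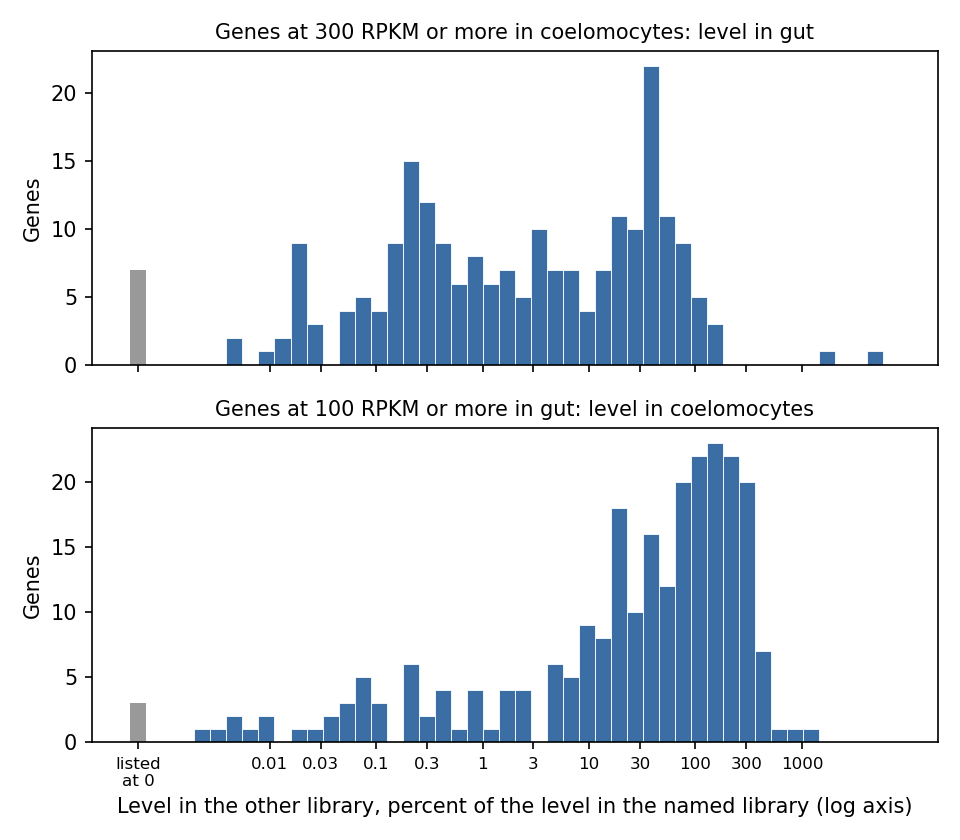
Number of genes (vertical axis) by their level in the other tissue as a percentage of the level in the named tissue (horizontal log axis), for the 222 genes at 300 RPKM or more in coelomocytes (top) and the 252 genes at 100 RPKM or more in gut (bottom); grey bars count genes listed at 0 in the other tissue. In the top panel 96 of the 222 genes lie under 1%, and in the bottom panel 42 of the 252 genes do.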

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

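No paired analysis was possible because each tissue had 1 library and no test between the tissues was run. For the same reason no replicate could be left out. Rescaling decided which tissue had more genes past the 4-fold rule. The genes higher in coelomocytes and in gut, 4042 and 1603 in the values as deposited, became 2607 and 2509 with trimmed mean scaling, 2143 and 2939 with upper-quartile scaling and 2503 and 2593 with equal summed RPKM. They became 1779 and 3502 when each library was divided by its sum without its 10 highest genes, a setting chosen after seeing the data. All 1603 genes higher in gut stayed so under these rescalings, because each shifts every ratio towards gut. A 2-fold rule gave 7269 and 2989 genes, an 8-fold rule 2110 and 897, and a minimum of 10 RPKM, also chosen after seeing the data, 2205 and 750. The pseudocounts of 0.1 and 1 and the minimum of 5 RPKM kept both counts within 1.5 times, with 5165 and 2221 genes at a pseudocount of 0.1 and 3149 and 1210 at 1. Median scaling also stayed within 1.5 times but moved the counts towards each other, to 2808 and 2364 genes, a coelomocyte share of 54.3%. Removing the minimum changed neither count, since the pseudocount already keeps genes under 1 RPKM from passing. The 4 named identifiers had absolute log2 ratios from 9.57 to 13.51 under the 8 pseudocounts and rescalings tried. Their direction was fixed by their selection for large ratios, so that it was kept is no test. A detection limit of 0.3 RPKM gave 18050 genes in coelomocytes and 17807 in gut, and a limit of 3 RPKM gave 9005 and 6059. With genes under 1 RPKM left out of the sums, the 10 highest genes held 14.9% in coelomocytes and 42.2% in gut, and the 100 highest held 40.3% and 56.8%, against 39.9% and 55.8% with all genes. Scaling on ribosomal protein genes, the gene list medians with their alternatives, and the limit of 10 reads per gene were not run, since no gene names and no read numbers were recovered. The unknown depth limits what low values can show.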

Other observations

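Position in the deposited table, which is sorted by neither column nor identifier, was related to expression. With the rows cut into 10 equal parts, the median coelomocyte value went from 0.33 to 2.66 RPKM and the median gut value from 0.36 to 1.05 RPKM between part 1 and part 8. In part 8, 592 genes were higher in coelomocytes and 115 in gut by the 4-fold rule, against 357 and 221 in part 1. In part 10, 51.9% of genes were listed at 0 in both tissues, only 9.20% reached 1 RPKM in either, and gut held more of the genes past the rule (112 against 45). What the rows were sorted by is not given in the sources used here.

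The tests in the next paragraphs were chosen after the results were seen. The rescaling to equal summed RPKM was among the alternatives fixed before the data were examined, though its use as a test came later. The test that divided each library by its sum without its 10 highest genes and the test by bins of mean level had their outcomes predicted before those values were computed. The predictions for all other tests were written afterwards, including the limits used for carry-over and for consecutive identifiers.

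The excess of genes higher in coelomocytes (71.6% of genes past the 4-fold rule) was not a feature of low values alone: among genes with a mean log2(RPKM + 0.5) of 3 or more over both tissues, 943 were higher in coelomocytes and 221 in gut, a coelomocyte share of 81.0%. Equal summed RPKM brought it to 49.1%, dividing each library by the share of its sum left by its own 10 highest genes to 54.8%, and dividing by the sum without those genes, which combines both shifts, to 33.7%. Each rescaling moves every ratio towards gut by 1 factor and so lowers the share by construction, which does not single out a cause. As a single factor would predict a like shift at every level, the median log2 ratio was compared over 6 bins of mean level. A range over 0.5 between bins was set to count against a single factor as the only source. A range under 0.3 was set to count as fitting it. The range over the 6 bins was 0.67, so by the set limit the test counted against a single factor. Without the lowest bin, where the pseudocount shrinks ratios, the range was 0.25 (0.77 to 1.02), under the limit for fitting. The question was left open only because that bin was set aside. Abundant gut transcripts that lower all other gut values, a different read denominator and higher expression of many genes in coelomocytes cannot be told apart, since no external standard in the table fixes the scale.

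Several of the most abundant coelomocyte genes had gut values near 0.217% of their coelomocyte level. This raised the hypothesis of a common source such as a small amount of coelomocyte RNA in the gut library. The fullest 2-fold window, 0.153% to 0.307%, held 30 of the 89 genes at 300 RPKM or more with a gut value above 0 and under 1%. Draws from a smoothed version of the same values (SD 1 on the log2 scale, as wide as the window) were scanned in the same way. They gave a median of 25 genes, and 9.20% of 10000 draws reached 30 or more. A concentration beyond that of a smooth spread was therefore not shown (14.2% of draws at the 100 RPKM limit and 6.95% at 1000 RPKM, in nested sets of genes). The draws keep part of any concentration in the values, so the comparison can miss one. The gut values in the window ran from 0.63 to 12.93 RPKM (median 2.185), so rounding to 2 decimals changed each of them little. The level limit and the window keep these values that high by selection, so their median is no separate test of rounding. Uniform carry-over of the coelomocyte library as the only source of the low gut values was compared with a Poisson bound (a value above 0 taken as at least 1 independent whole read, Bonferroni-adjusted). By more than this bound allows, 13 of 215 genes lay below 0.217%, which passed the number set afterwards for counting against this source. They stood at 375 to 836 RPKM in coelomocytes and at 0.02 to 0.14 RPKM in gut. Against the lower end of the window, 0.153%, 4 genes did. A further 7 genes, at 320 to 917 RPKM in coelomocytes, were listed at 0 in gut and were not among the 215. Amplified duplicates or reads split between gene models would weaken the bound, and the share was taken from the same data, so the question stays open. Coelomocytes in the gut that differ from the isolated phagocytes and low expression by gut cells stay open.

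The tissue ratios of genes with consecutive identifier numbers were weakly correlated. Across 9950 pairs with both genes at 1 RPKM or more in either tissue, the log2 ratios correlated at r = 0.16, against 0.05 for identifiers 2 apart and 0.03 for those 3 apart, and 1000 shuffles of the identifiers gave at most 0.041. Duplicated gene models taking the same reads could contribute, since 7.98% of consecutive pairs had values within 1.5-fold in both tissues, compared with 5.13% of pairs 10 apart. Such near-equal pairs are argued against as the only source, because without them the correlation was 0.1134, still above every shuffle. Duplicated models whose values differ by more than 1.5-fold were not removed by this step, so they stay open. Partial sharing of reads, transcripts split over several models and joint expression of neighbouring genes stay open, and whether consecutive numbers are neighbours in the genome was not tested.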
